A study of Sparus aurata with 9 samples.

How the data were processed

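Liver RNA of gilthead sea bream was measured on 9 one-colour (Cy3) Agilent arrays, 3 pools per group. Per the labels' protocols, RNA was extracted from each of 27 fish, 3 fish were combined per pool, and 200 ng of total RNA was reverse transcribed together with Agilent's one-colour spike-in RNA. Fish of a condition shared tanks, so the tank lies within the treatment and cannot be told apart from it. P-values measure the spread between pools, and the pools are not known to be separate exposures. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, and the deposited scanner files hold spot intensity on a linear scale, with a processed signal already background-subtracted. The authors' value table holds log2 values. Set against the scanner files, each of its values was the log2 of the background-subtracted signal, with empty cells where that signal was 0 or less, so it carries no scaling between arrays. Its column medians were 7.01, 6.56 and 6.55 for the controls, 7.01, 6.69 and 7.04 at 0.5 µg/L, and 7.33, 7.16 and 6.97 at 50 µg/L. These values rise with expression, and neither scale, centring nor direction stays unknown.

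From the 45220 spots, the 43803 that are not controls were used. The log2 processed signal was taken relative to each array's 75th percentile. Spots flagged as outliers were left out, and the spots of a probe were averaged. Where all spots of a probe on an array were flagged, they were used all the same. Flagged values therefore stayed in for probes with 1 spot. Of 28793 probes, 15785 had 1 spot, 12854 had 2 and 154 had 15. No spot was saturated. The 9280 probes well above background on all 3 arrays of at least 1 group were kept, and 6759 of them were so on all 9 arrays. Between 26.0% and 47.1% of probes were well above background per array. The SD between spots of one probe was 0.24 to 0.37 on the log2 scale. Between pools it was 0.37 in controls, 0.41 at 0.5 µg/L and 0.43 at 50 µg/L.

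The 3 comparisons came from one limma 3.58.1 fit (R 4.3.3, lmFit and eBayes, 4.12 prior degrees of freedom) over all 9 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a probe was not well above background on any array of a group, a bound on the fold was computed as the brighter group's mean over the dimmer one's. The dimmer mean takes on each array the higher of the probe's own signal and the lowest signal among probes well above background. For the named probes of this kind the bound equalled the measured fold. The fold is therefore given as measured and is not a lower bound.

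The 3 slides coincided with the pool numbers, and each slide held 1 array of each group. The control, 0.5 and 50 µg/L arrays lay at positions 1, 2 and 3 on every slide. The slide was tried as a fixed and as a random block.

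Sequence and probe names were looked up in the RefSeq gene table of assembly fSpaAur1.1, and 0 matched. The 29 lists of pathway and cell type genes fixed before the data were examined, and the rule for named genes, could therefore not be applied. Instead, at most 2 sequences that were higher and 2 that were lower are named per comparison. These are the called probes with the largest fold, or, with no calls, those with the smallest p, at 1 probe per sequence.

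The scripts were tested on simulated data with 200 of 9280 probes changed by 1.5, 2, 3 or 4-fold, in 10 simulations per comparison. Each probe was drawn independently with the variance that limma had moderated across probes. The shares below hold for that setting, and recovery is lower where fewer probes change or variances differ more. Between 50 and 0.5 µg/L, 36% of 2-fold and 86.6% of 3-fold changes were recovered, and 5.55% of calls were false. With the slide as a block, recovery was 28.6% and 85.4%. With no change, the tests called at most 1 probe.

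Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, other filters, blocks and variance models, array weights, 2 groups alone, each array left out, the deposited values, other thresholds and sequences in place of probes. Normexp was run on the median spot signal, because the scanner files used here carry no mean signal. Scaling to the 6 of 10 spike-ins well above background on all arrays, and the ratio to them as a covariate, were added after seeing the data.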

Results

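Juvenile gilthead sea bream (Sparus aurata), a marine teleost, were kept for 24 h in seawater with gold nanoparticles (AuNP) at 0, 0.5 or 50 µg/L, and the RNA of their livers was measured on arrays. The lower concentration is one predicted for the environment, and the higher one is a spiking dose. Each of the 3 groups held 9 fish of about 50 g, whose RNA was combined into 3 pools of 3 fish, so that n = 3 pools per group. The array carried 28793 probes for 15156 sea bream sequences, of which 6057 were assembled contigs and 9099 single clones. The files pair none of these sequences with a gene name, so changes are given as counts of probes and sequences, with few identifiers, and no pathway or cell type could be read. The control pools had 13557, 9584 and 10252 probes well above background. The pools at 0.5 µg/L had 11962, 9598 and 7473, and those at 50 µg/L had 9382, 10202 and 8443. Arrays of one group correlated with a median r of 0.965 across 9280 kept probes. The number of arrays limits the precision of every value.

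Along the first principal component, which held 27.3% of the variance, the 3 pools at 50 µg/L lay apart from the other pools. Control pool 1 lay between them and the pools at 0.5 µg/L, and the remaining controls lay among the latter. The 50 µg/L pools scored 23.8, 26.8 and 28.5, and the 0.5 µg/L pools scored -29.0, -11.7 and -20.1. The controls scored 8.47, -12.7 and -14.2. Pool 2 at 50 µg/L stood alone on the second component at 38.4, which held 18.6% of the variance.

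**Figure D1:**
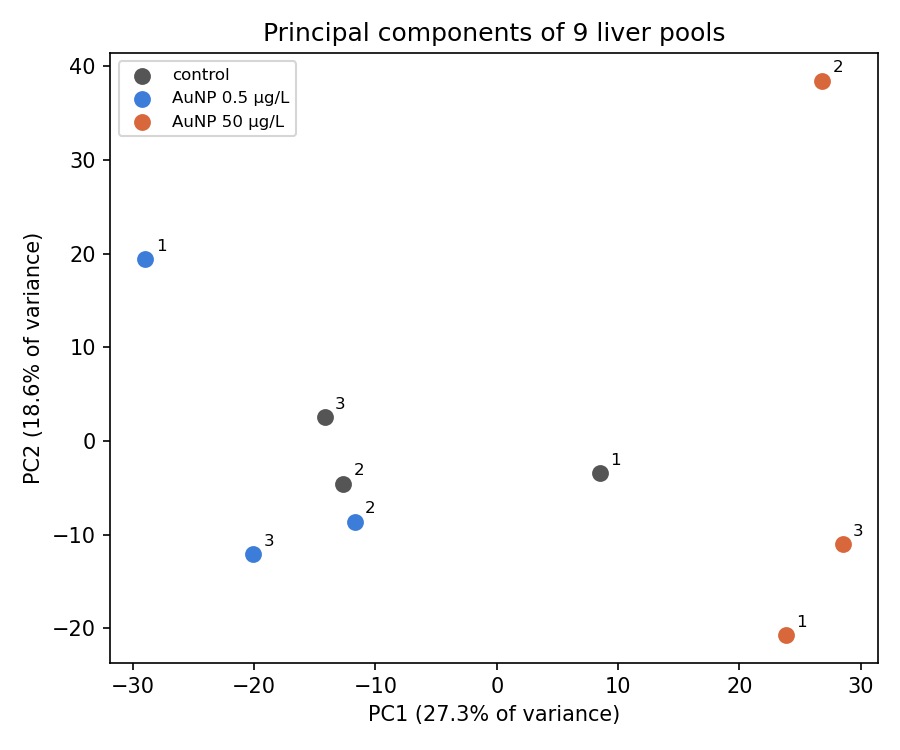
Scores of the 9 liver pools on the first (x axis) and second (y axis) principal components of 9280 probes, in units of log2 signal; colours mark the groups and digits the pool. The 50 µg/L pools lie at 23.8 to 28.5 on the first component, and pool 2 of that group lies at 38.4 on the second.

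The first comparison asked what the low, environmentally predicted concentration did to liver transcripts against unexposed fish. No probe passed at 0.5 µg/L: limma called 0 of 9280 probes at an adjusted p under 0.05, and the smallest adjusted p was 0.669. At an unadjusted p under 0.05 there were 509 probes, where chance would give 464, with 197 higher and 312 lower. The 3 probes of the contig Seabream_2006-01-03-CL4987Contig1 had log2 differences of -0.89, -0.98 and -1.06. The probe with the smallest p had a log2 level of 4.44 ± 0.22 in controls, 3.45 ± 0.21 at 0.5 µg/L and 4.60 ± 0.05 at 50 µg/L (SD, n = 3 each). Between both concentrations, its probes had adjusted p of 0.0386, 0.0301 and 0.0628 in limma (probes CUST_9343_PI419285025, CUST_9344_PI419285025 and CUST_9345_PI419285025). The clone cDN02P0003F20.F.ab1 had log2 differences of 0.52, 1.02 and 0.67 over its 3 probes. Neither sequence passed against controls, since limma gave its probe with the smallest p an adjusted p of 0.669. In simulated arrays with the spread of these pools, 40% of probes changed 2-fold and 88% of those changed 3-fold were recovered in this comparison.

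The second comparison set the high concentration against the same controls. At 50 µg/L, limma again called 0 of 9280 probes, with a smallest adjusted p of 0.249. Here 1175 probes had an unadjusted p under 0.05 beside 464 by chance, 415 of them higher and 760 lower. The clone cDN08P0005P12.F.ab1 had a log2 difference of -2.32 ± 0.35 (SE), with an adjusted p of 0.249. Its log2 level was 0.76 ± 0.25 in controls and -1.55 ± 0.84 at 50 µg/L (SD, n = 3), where 1 of 3 arrays measured it well above background. The 3 probes of the contig Seabream_2006-01-03-CL1146Contig1, which held the smallest p among higher probes, disagreed, with log2 differences of 1.04, 0.23 and -0.40. The contig Contig2410, with 1 kept probe, had a log2 difference of 1.82 ± 0.35 (SE) and was well above background on 1 control array and on all 3 arrays at 50 µg/L. The probes of a further clone, cDN14P0006C16.F.ab1, disagreed. Its first probe had a log2 difference of 0.27. Its second was not well above background on any array at 50 µg/L and measured 4.50-fold lower there (limma adjusted p = 0.249). The third had a log2 difference of -2.32 and was well above background on 1 array at 50 µg/L. A fit of these 2 groups alone called 3 probes, all higher at 50 µg/L.

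The third comparison asked whether the 2 concentrations differed from each other, and it was the only one with calls. Limma called 93 of 9280 probes, from 65 sequences, of which 84 rose and 9 fell at 50 relative to 0.5 µg/L. Dim probes were frequent among them: 46 of the 93 (49.5%) were well above background on all 9 arrays, against 72.8% of kept probes. With only probes well above background on all 9 arrays tested, limma called 64, of which 52 rose and 12 fell. The wider set of 1879 probes at an unadjusted p under 0.05, where chance would give 464, leaned the other way, with 859 higher and 1020 lower. The direction of such a lean depends on the processing. The median log2 difference over all kept probes was -0.08 as reported and -0.04 with quantile normalization. It was 0.09 with median centring, 0.03 with normexp and 0.51 with spike-in scaling. The probes that rose had a median fold of 2.78, from 1.89 to 11.5, and those that fell had a median of 2.16. The clone cDN10P0005N01.F.ab1 rose on each of its 3 probes, by 2.84, 2.78 and 2.77 on the log2 scale. The probe with the largest rise had a log2 level of 2.56 ± 0.36 at 0.5 µg/L and 5.41 ± 0.24 at 50 µg/L (SD, n = 3), with an adjusted p of 0.0227. Controls lay between them, at 4.22 ± 0.88. Contig1412 rose 11.5-fold (adjusted p = 0.0463), and was well above background on 1 array at 0.5 µg/L and on 3 at 50 µg/L. Its log2 level was -1.57 ± 1.49 at 0.5 µg/L and 1.96 ± 0.25 at 50 µg/L (SD, n = 3). The log2 difference of 3.53 was 2.99 without pool 2 at 0.5 µg/L and 4.38 without pool 3 at 0.5 µg/L. The clone cDN01P0004I17.F.ab1 fell by 1.41 on the log2 scale, from 2.82 ± 0.54 to 1.41 ± 0.14 (SD, n = 3; adjusted p = 0.0455). Of the 3 probes of the clone cDN07P0002M13.F.ab1, 1 was not well above background on any array at 50 µg/L. It measured 2.55-fold lower there (limma adjusted p = 0.0391). The others were 1.47-fold and 1.68-fold lower and did not pass (adjusted p = 0.230 and 0.140), with 2 and 1 arrays well above background at 50 µg/L.

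**Figure D2:**
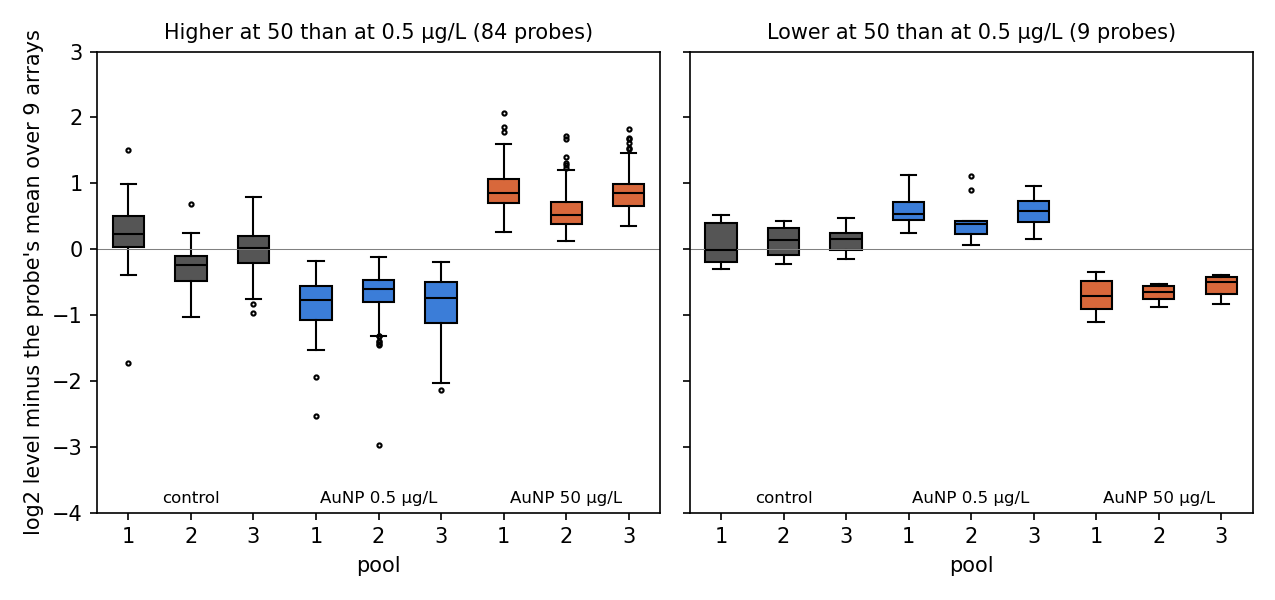
Log2 level of each called probe minus its mean over the 9 arrays (y axis) for each pool (x axis), shown as boxes of the median and quartiles, with whiskers to 1.5 times the box height and points beyond. The 84 probes that rose lie highest in the 3 pools at 50 µg/L and lowest in the 3 pools at 0.5 µg/L, and the 9 that fell lie the other way round.

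Control means lay between those of both exposed groups for 92 of the 93 called probes. Of the 84 that rose, all 84 had a lower mean at 0.5 µg/L than in controls and a higher mean at 50 µg/L. Their median log2 difference from controls was -0.69 at 0.5 µg/L and 0.76 at 50 µg/L. Of the 9 that fell, 8 had the control mean between the exposed groups. A set chosen for its gap between the exposed groups tends to have the controls in the middle by that choice alone. No probe of the set passed against controls at either concentration. Of the 42 called sequences with over 1 kept probe, 40 had all probes on the same side, and 46 of 49 uncalled probes of these sequences went the way of the called ones. Across all 2312 sequences with over 1 kept probe, 79.1% had all probes on the same side.

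Each slide held 1 pool of each group, so the difference could be taken within slides. The median within-slide log2 difference of the 84 probes was 1.57, 1.08 and 1.57 on slides 1, 2 and 3. In all 84, every pool at 50 µg/L lay above every pool at 0.5 µg/L. A positive difference on each slide therefore followed from the choice of these probes and is no replication. Over all 9280 probes, the differences of slides 1 and 2 correlated at 0.10, those of slides 1 and 3 at 0.41 and those of slides 2 and 3 at 0.31. With the slide as a block, limma called 0 probes, with a smallest adjusted p of 0.0548. The count fell to 0 without pool 1 at 0.5 µg/L, pool 1 at 50 µg/L or pool 3 at 50 µg/L, to 11 without pool 3 at 0.5 µg/L and to 41 without control pool 3. It was 0 with the deposited values, with normexp background correction or without the filter on dim probes. Each group lay at 1 position of its own on every slide, so position and group cannot be told apart. The same holds for the tanks, which fish of a condition shared. A test of any difference among the 3 groups (limma's F) called 0 probes, with 1447 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0777.

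The fold changes of both concentrations, each against the same 3 control pools, correlated weakly across the 9280 probes, with Pearson r = 0.15 and Spearman rho = 0.09. Probes are not independent replicates. In 100 simulations of unchanged groups that shared 3 controls, r was 0.50, between 0.46 and 0.53. The simulations drew each probe independently, so this range understates the spread that correlated probes give. Among regroupings of the 9 real arrays, the real grouping left out, r ran from 0.148 to 0.721. The observed covariance was 0.0223 and the simulated one 0.0436, a difference of -0.0212. The same sign was seen in 52.8% of probes, against 66.6% in the simulations. At an unadjusted p under 0.05, 29 probes were higher at both concentrations and 52 lower at both, where independent lists would share 8.81 and 25.6, and 58 went opposite ways. On the same side at both concentrations were 81 probes, beside a mean of 85.04 in simulated unchanged groups with shared controls. The real lists held 509 and 1175 probes, where chance gives 464 in an unchanged group. Longer lists share more probes, so both counts cannot be compared directly. No split of 3 controls leaves at least 2 for each concentration, and none was made.

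The amount of signal relative to the added spike-in RNA also parted the exposed groups. The log2 75th percentile minus the mean log2 signal of 6 spike-ins was -4.88 ± 0.09 at 50 µg/L, -5.47 ± 0.18 at 0.5 µg/L and -5.32 ± 0.46 in controls (SD, n = 3). Control pool 1, at -4.80, lay among the 50 µg/L pools, at -4.97 to -4.79. Control pool 1 and the 50 µg/L pools were also the only ones with a positive score on the first principal component. Both terms entered the gap. The spike-ins stood at 12.99, 13.16 and 12.57 at 50 µg/L and 13.60, 13.01 and 13.07 at 0.5 µg/L. The 75th percentiles were 8.12, 8.19 and 7.78 at 50 µg/L and 7.93, 7.66 and 7.70 at 0.5 µg/L. The difference of 0.59 between both exposures had an exact two-sided permutation p of 0.10, the smallest that 3 against 3 pools allow. Against controls the difference was 0.45 at 50 µg/L (exact p = 0.30) and -0.14 at 0.5 µg/L (exact p = 0.80). Every fold change above is relative to the 75th percentile, and scaling to the spike-ins would add 0.59 to each log2 difference between 50 and 0.5 µg/L.

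**Figure D3:**
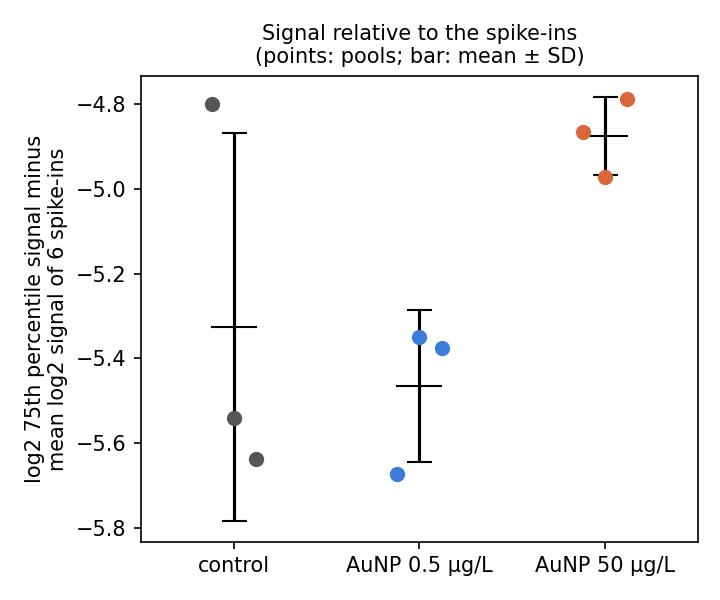
The log2 75th percentile of each array minus the mean log2 signal of 6 spike-ins (y axis) in the 3 groups (x axis); points are pools, and bars are the mean and SD. The 50 µg/L pools average -4.88 and the 0.5 µg/L pools -5.47.

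Pool 2 at 50 µg/L stood apart by a set of probes much brighter there than in any other pool. On its array, 120 probes of 87 sequences were at least 8-fold brighter than on any of the other 8 arrays, beside 13 to 68 such probes on each other array. Of its 98 such probes with other probes for the same sequence, 65, from 32 sequences, had those at least 2-fold higher there too, which held for 0 to 4 probes on each other array. The 3 probes of the clone cDN03P0003F23.F.ab1, singled out after its values were seen, stood at log2 levels of 8.17, 8.29 and 8.02 there and were not well above background elsewhere. Only 2 of the 120 probes entered the tests above, and without this pool limma called 89 probes between the 2 concentrations, 57 of them among the 93.

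**Figure D4:**
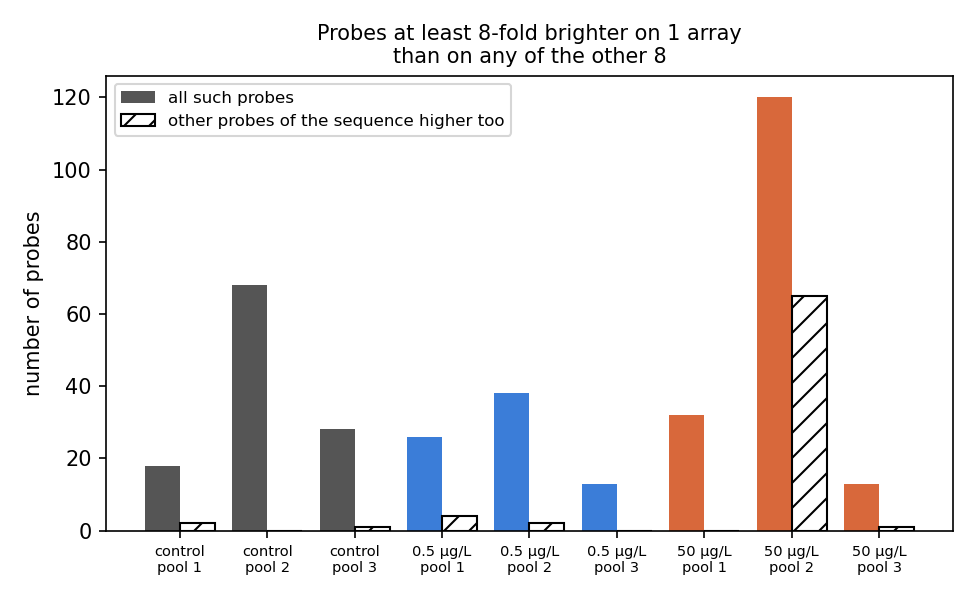
Number of probes at least 8-fold brighter on 1 array than on any of the other 8 (y axis, filled bars) for each pool (x axis), and how many of them had the other probes of their sequence at least 2-fold higher on that array (hatched bars). Pool 2 at 50 µg/L had 120 such probes, 65 of them with other probes higher too.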

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

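The counts of called probes over other splits of the arrays were fixed before their results were seen. The tests of slides, array position, spike-ins and single spots, and the regroupings behind the correlation of both concentrations' changes, were chosen after the results were seen.

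A signal appeared among probes that the filter kept out of every comparison: 118 such probes were at least 8-fold brighter on the array of pool 2 at 50 µg/L than on any other array, all controls included. Blemishes of single spots are argued against for probes with 2 spots, since both spots were bright for 41 of 43 (95.3%). Control pool 2 had the next highest number, 68 probes, but there 0 of 9 probes with 2 spots had both bright. Its bright spots lay a median of 1 spot from the nearest other one, against 12.5 for random spots (permutation p = 0.001, the smallest that 1000 random sets can give), which is consistent with a blemished area. Bright spots of pool 2 at 50 µg/L lay nearer together than random spots too, though by less (7.84 against 9.39, permutation p = 0.019), and those of each other array at a permutation p of 0.001, so blemishes stay open for probes with 1 spot and no support from other probes. RNA of another tissue or cell type in pool 2 at 50 µg/L stays open as a hypothesis, as does a response of single fish, because 0 probes have a gene name by which markers could be looked up.

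The gap of 93 probes between both concentrations was the largest count over 10 splits of the 6 exposed arrays, and the highest other split called 0, but 10 splits are too few for a share under 0.05, the real split being 1 of them. An additive offset between slides cancels from the group difference by design, because each slide held 1 array of each group. The within-slide differences of all probes correlated between slides at a mean of 0.27 (SE 0.09, 3 pairs). The pairs share slides, so this SE takes dependent values as independent. An effect of array position repeated on every slide would give such a correlation too, so this test of slides decides nothing. The bound for this test was revised once after its result was seen, from every pair over 0.1, which the lowest pair met narrowly at 0.102, to a mean more than 2 SE over 0. A slide block cannot change any fold in this balanced design. With it, the median SE of the 93 probes moved from 0.23 to 0.24, beside a median absolute log2 difference of 1.41, and the calls ended with 4 instead of 6 residual degrees of freedom. A higher amount of labelled RNA relative to the spike-ins may account for part or all of the gap and stays open. Within groups the called probes rose by 0.40 ± 0.17 (SE) per log2 unit of that ratio (exact p = 0.11), where the gap would need 2.40. Control pool 1 set most of that precision, without which the slope was 0.38 ± 0.47 (SE). These probes were called for a large gap and a small spread within groups, which by itself favours a low slope, so the slope excludes nothing; an earlier bound that took it as excluding the whole cause was dropped for that reason. The position on the slide, which all 3 groups kept for themselves, the tanks and the nanoparticle concentration cannot be told apart.

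Where the real count was 0, every split calls at least as many by construction, so the splits decide nothing. This covers both comparisons against controls (10 of 10 splits, highest other 0) and any difference among the 3 groups (100 of 100 splits, highest other 1).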

How the results depend on the processing

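The spike-in settings were chosen after seeing the data. Limma's 0 calls at 0.5 µg/L against controls held under every setting but the threshold of an unadjusted p under 0.01 with 1.5-fold, which passed 112 probes where chance gives 92.8 at that p alone. At 50 µg/L against controls that threshold passed 270, the 2 groups alone gave 3, scaling to the spike-ins gave 2, and the other settings with all 9 arrays 0. Between the concentrations, 93 became 0 with normexp, without the dim filter, with the replicate block, with the deposited values or with the spike-in ratio as a covariate. The 93 became 43 with the 2 groups alone and 53 with the slide as a random block. They became 256 with median centring, 296 with array weights and 563 with spike-in scaling (562 higher). With sequences as the unit, 56 of 5191 were called, beside the 65 sequences that the 93 probes came from. An adjusted p under 0.10 passed 420 (252 higher) and the unadjusted threshold 698 (398 higher). With the covariate all 93 probes kept their direction, at a median absolute log2 difference of 1.21 in place of 1.41, while the median SE rose from 0.23 to 0.32. The F test called 63 with median centring, 11 with array weights, 164 with spike-in scaling, 65 at an adjusted p under 0.10 and 463 at the unadjusted threshold. The correlation of both concentrations' changes, 0.15, was 0.52 without the dim filter, where simulated unchanged groups gave 0.50, and 0.27 with array weights, for which no such value was simulated. For these results the cause was not tested, beyond the residual degrees of freedom that blocks and smaller sets of arrays take.

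Leaving out each array in turn, with the kept probes fixed, gave 0 to 0 probes at 0.5 µg/L against controls, 0 to 1 at 50 µg/L against controls (1 without pool 1 at 50 µg/L), 0 to 109 between the concentrations and 0 to 16 in the F test. The correlation ranged from 0.0858 without pool 2 at 0.5 µg/L to 0.368 without control pool 1. The F test called 11 without control pool 1, 16 without control pool 2 and 1 without pool 1 at 50 µg/L. In the group left with 2 pools, these were assumed to vary like the others.

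No pairing by pool number was seen, and pool number cannot be told apart from the slide. Deviations of same-numbered arrays correlated at -0.15 to 0.12, only 1 of 9 pairs over 0.1, and others at -0.19 to 0.26. The replicate block changed calls only between the concentrations. Of 304 alternative values of 12 named probes, 0 reversed and 9 gained a call, most by unadjusted p. Only called probes could lose one: per probe, 16, 9, 16 and 16 values did (57) and 9, 17, 10 and 9 did not. Leaving out saturated probes removed none and tests nothing. The gene list alternatives were not run. Signal over background limits the tests to the 9280 kept of 28793 probes.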

Other observations

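The regroupings of the arrays for the correlation of both changes, and the simulations with 2 controls or without the filter, were chosen after the results were seen.

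Among the 9280 kept probes, the one with the largest SD between pools belonged to Contig3669, chosen after its values were seen. Its 3 probes agreed on each array, and their mean log2 levels were 3.14, 7.62 and 2.98 in the control pools and 7.53, 5.38 and 6.66 at 50 µg/L. At 0.5 µg/L it stood at 8.26 in pool 3 and was not well above background in pools 1 and 2.

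Between controls and 0.5 µg/L, 63 probes were well above background in all 3 control pools and in no pool at 0.5 µg/L, and 1 the other way round. Between controls and 50 µg/L, 204 probes were so in all 3 control pools and in no pool at 50 µg/L, and 2 the other way round. Between the concentrations, 56 probes were so in all 3 pools at 50 µg/L and in no pool at 0.5 µg/L. The other way round there were 17. No count expected by chance was computed for these. They depend on how many probes each array detected, a mean of 11131 in controls, 9678 at 0.5 µg/L and 9342 at 50 µg/L. Against controls, limma called 0 probes at either concentration, with or without the dim filter. The median log2 differences were -0.03 at 0.5 and -0.10 at 50 µg/L with it, and 0.21 and 0.20 without it. Loss of transcripts on exposure is therefore not shown by these counts. The number of detected probes per array was not told apart between groups by exact permutation tests, with p = 0.50 for 0.5 µg/L and 0.20 for 50 µg/L against controls and 0.90 between the concentrations, where 0.10 is the smallest possible.

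A hypothesis formed after seeing the data is that both concentrations moved the liver away from controls in opposite directions. It was not tested directly. The correlation of both changes was above 0, though shared controls raise it. At 0.5 µg/L limma gave 509 probes an unadjusted p under 0.05, beside 464 by chance, so little move from controls was seen there. Among 100 regroupings of the 9 arrays, 2 gave a correlation of both changes as low as the real 0.15, the real one included. The lowest other was 0.148, below the real value, and the median of the others was 0.52. The correlation was singled out because it was low, so this share excludes nothing, and an earlier bound that took it as excluding chance was dropped for that reason. A low value may also come from array position or the tanks. A move of 1 exposed group alone would lower the correlation but, on average, not the covariance. The covariance was 0.0223, beside 0.0436 (0.0388 to 0.0498) in simulated unchanged groups. That range understates the spread of correlated probes, so such a move is not excluded as a part of the cause. The correlation was 0.37 without control pool 1, 0.17 without control pool 2 and 0.25 without control pool 3. For each, simulated unchanged groups sharing 2 controls gave 0.60. Without the filter on dim probes it was 0.52, beside 0.50 in simulated unchanged groups, so the low value was not seen over all 28793 probes.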
